A study of Thunnus orientalis with 36 samples.

How the data were processed

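Hearts of the Pacific bluefin tuna (Thunnus orientalis), a fish that keeps its swimming muscle warmer than the water while its heart works at water temperature, were profiled on a custom 2-colour Agilent array. Per the labels, 12 fish were held at 14, 20 or 25 °C, 4 at each temperature, and RNA was taken from the atrium and from the compact and spongy layers of the ventricle of each fish. That gave 36 arrays in 9 groups of 4. The label of each array names its fish, tissue and temperature, so the replicate is the fish, and the labels tie the 3 arrays of a fish together. Cy5 labelled the sample and Cy3 labelled a reference pool mixed from all samples, the same way round on all 36 arrays. No dye was swapped, so a probe's own dye bias cancels only in differences between samples.

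Per the labels' protocols, total RNA was extracted with Trizol from tissue fixed in RNAlater, amplified by in vitro transcription and labelled through amino allyl groups. Per the file headers, the deposited scanner files hold intensity values: the mean brightness of each spot and the median of its local background, in scanner units, together with signals that Agilent Feature Extraction 9.5.3 had background-subtracted, detrended and dye-normalised. The deposited series table holds log10 ratios of Cy5 over Cy3. Every value in it equals the log10 ratio of the same spot in the scanner files, with a largest difference of 0, so its scale and direction are settled, and its column medians ran from -0.09 to 0.051. Any further centring by the authors is not given in the sources used here.

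The array carries 21024 probes of 50 bases, each spotted in 2 places, and 1417 control spots. Probe names share a stem for each target sequence, which gives 7094 targets, 6837 of them with 3 or more probes. There are 20195 distinct probe sequences, so 829 probes repeat the sequence of another. The files pair no probe with a gene name, position or description, and no reference for this species was used here. The 28 gene and marker lists and the naming rule that had been fixed by gene symbol could therefore not be applied, and targets are given by their identifiers. The rule that took their place was chosen after the data were seen. It was revised 2 times after the targets it picked were seen. A first form used the mean of a target's probes in 9 contrasts. The next form used the brightest probe in 2 contrasts and barred shared sequences, and it picked targets with too few unmarked arrays in a group. It covers targets with at least 3 probes, all past the threshold in 1 direction, well above background on at least 3 of the 4 arrays of every group compared, never saturated and sharing no sequence with another target. The brightest probe of the target, which stands for it, had to be unflagged and well above background on every array compared. The 2 largest rises and the 2 largest falls are named for the contrast of 25 with 14 °C and for the contrast of atrium with compact layer, 8 targets in all.

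Background was corrected with normexp and an offset of 50, and each array was normalised by loess in limma 3.58.1 under R 4.3.3. Control spots had weight 0 in the loess. Spots with a population or uniformity outlier mark were left out, a median of 1.54% and at most 7.71% of an array's spots, while saturated spots were kept. The spots of a probe were averaged. A probe was tested if its sample channel was well above background, in both spots, on at least 3 arrays of at least 1 group, which held for 19605 probes and left out 1419. The log2 ratios of sample over reference were fitted with limma as 9 group means, with the fish as a random block, followed by eBayes. Adjusted p values are Benjamini-Hochberg values over the probes of each contrast, and 0.05 was the threshold. The tissue by temperature terms were tested together by a moderated F test. Within-tissue contrasts and means over tissues or temperatures all come from this 1 fit. Counts of targets come from the same fit on the mean of a target's probes.

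The pairing of tissues by fish comes from the labels. Deviations from the group means of arrays of 1 fish correlated at 0.0211 on average over 36 pairs, the block correlation was -0.00651, and arrays that share only a number across temperatures correlated at 0.0248. The fit thus treated the 3 arrays of a fish as nearly independent. Its p values over tissues rest on 12 arrays from 4 fish at each temperature. Duplicate spots of a probe correlated at a median of 0.823 within an array. No pair of arrays of 1 group was identical, the highest correlation being 0.956. The lowest correlation between any 2 arrays was -0.646, between a spongy layer at 14 °C and an atrium at 25 °C. The dyes are stated in the labels and ratios against a pool of all samples can oppose each other, so the direction was kept.

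The scanner files give the scan time, and the arrays fall on 6 scan days, named A to F here. Days A, B and F held only arrays from 14 °C fish, days C and D only arrays from 25 °C fish, and day E all 12 arrays from 20 °C fish. Each day thus held 1 temperature, although 14 and 25 °C spanned more than 1 day, so no temperature contrast lies within a day. For temperature contrasts the scan day was fitted as a random block in place of the fish. The size of that block rests on the groups at 14 °C, the only groups that spanned more than 1 day. It cannot remove an effect of the days from a temperature contrast. Tissue contrasts were repeated in a fit of tissue with the scan day as a fixed block, without temperature terms, and within the days that held several tissues. Scans over 1 hour apart form separate sessions, 7 in all. Day E had 2 sessions, 1 with all atrium arrays and the other with all compact and spongy arrays, and each other day was 1 session. The slide of each array was not used here. The number of arrays limits the precision of every value.

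The fit was tested on simulated data over 17998 probes, with 66 or 67 probes changed at each of 3 sizes in each simulated comparison. For 25 minus 14 °C over the tissues it recovered 88.1% of changes of 0.5 on the log2 scale and 100% of changes of 1 and 2. For 25 minus 14 °C in the atrium it recovered 77.6%, 95.5% and 100%, for the tissue by temperature terms 50.7%, 82.1% and 97%, and for atrium minus compact layer 91%, 97% and 100%. Probes with no simulated change made up 8.12%, 5.16%, 4.97% and 4.42% of the calls in these 4 tests, 29, 19, 8 and 15 probes. In this 1 run, at a threshold of 0.05, the share over the tissues exceeded its nominal level. The simulated noise was drawn independently for each array, with no effect of fish, scan day or session and with few probes changed. The shares recovered and the shares of unchanged probes therefore need not hold for the real arrays.

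Alternatives fixed before the data were examined were the Agilent processed signals, no background subtraction, median centring in place of loess, Aquantile between arrays, no filter, a filter for probes well above background in both channels on all 36 arrays, the fit without the fish, the replicate number as a fixed block, the scan day as a block, array weights, fits of the compared groups alone, the series table centred on each array's median, and leaving out each fish in turn. Alternatives added after the data were seen were an offset of 0, removal of each array's trend with probe GC content, leaving out the atrium array of fish 4 at 20 °C, leaving out the 4 arrays of day F, the scan session as a random block, and, for the tissue contrasts, the scan day or session as a fixed block.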

Results

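The series asked how the transcripts of the tuna heart respond to cold and warm acclimation in its 3 muscle compartments. The 36 arrays covered the atrium, the compact layer and the spongy layer of the ventricle, 3 compartments in each of 12 fish, with 4 fish at 14, 20 and 25 °C. In the teleost ventricle the compact layer is the outer wall with coronary supply, and the spongy layer is the inner meshwork bathed in venous blood. Signal differed between the groups. The share of sample spots well above background averaged 94.6% ± 0.802 (SD, n = 4) in the atrium at 20 °C and 74.8% ± 8.77 in the atrium at 25 °C, but 37.2% ± 14.8 in the compact layer at 25 °C and 37.8% ± 9.42 in the compact layer at 14 °C. The median signal of the reference pool, which is the same RNA on every array, ran from 54.1 to 155.3 scanner units on the arrays of 14 °C fish, from 140.5 to 590.1 on those of 20 °C fish and from 115.6 to 189.1 on those of 25 °C fish. Brightness thus differed between the temperatures, and so did the scan day. In the compact layer the reference signal was alike at 20 and 25 °C but lower at 14 °C. It averaged 87.5 ± 26.9 there at 14 °C, 149 ± 5.99 at 20 °C and 150 ± 23.1 at 25 °C. At 20 °C it averaged 494 ± 108 in the atrium and 264 ± 35.1 in the spongy layer.

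**Figure D1:**
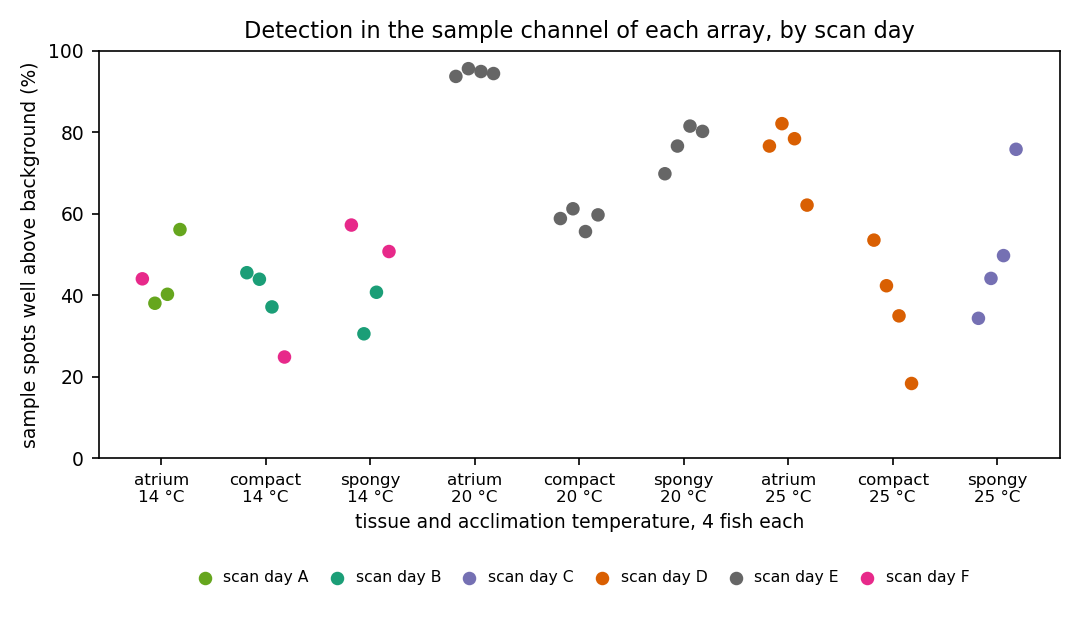
Percentage of sample spots well above background (vertical axis) on each of the 36 arrays, by tissue and acclimation temperature (horizontal axis); each point is 1 fish, fish 1 to 4 from left to right, coloured by scan day. The atrium arrays at 20 °C lie between 93.7% and 95.6%, and the compact arrays at 25 °C between 18.3% and 53.5%.

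The atrium at 25 °C stood apart from every other compartment and temperature. The first principal component of the log2 ratios held 49.4% of the variance, and the atrium arrays at 25 °C averaged 85.6 ± 8.6 (SD, n = 4) on it, against 12.2 ± 3.68 for the compact layer and 10.1 ± 0.513 for the spongy layer at 25 °C. The atrium array of fish 4 at 20 °C lay at 73.4, while the other 3 atria at 20 °C lay between -26.3 and 0.0861. The 4 arrays of 14 °C fish scanned on day F lay between -61.5 and -29. The mean correlation between arrays of 1 group was 0.702 and that between arrays of different groups 0.134.

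**Figure D2:**
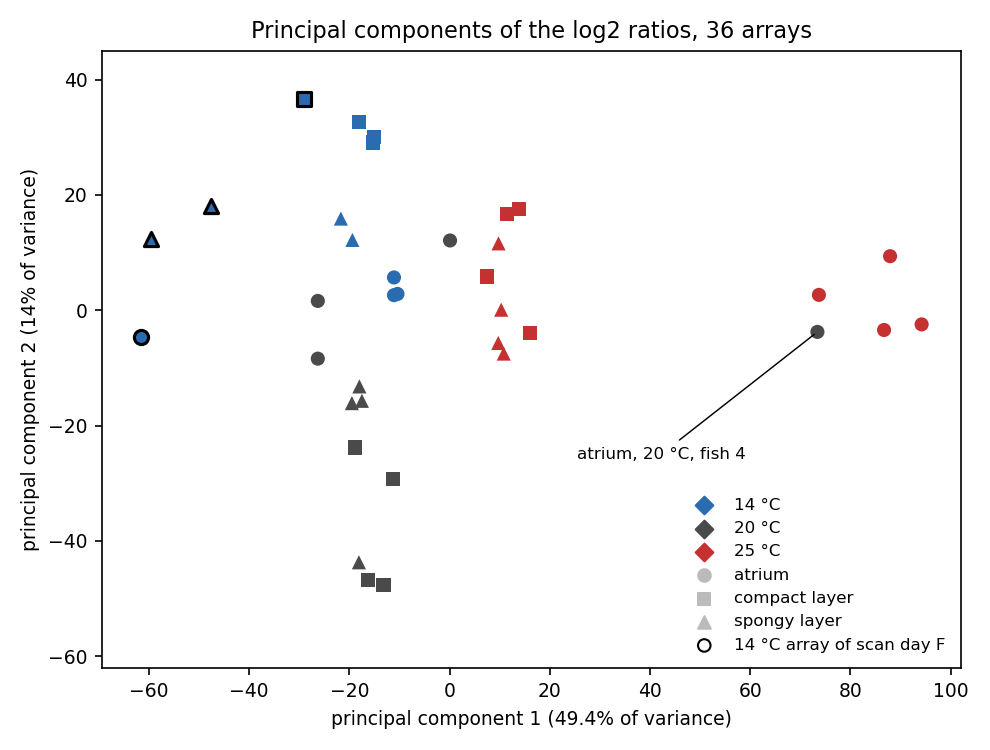
Scores of the 36 arrays on the first (horizontal axis, 49.4% of variance) and second (vertical axis, 14% of variance) principal component of the log2 ratios, coloured by temperature, with a symbol for each tissue and a black outline for arrays of 14 °C fish scanned on day F. The 4 atrium arrays at 25 °C lie between 73.7 and 94.2 on the first component, next to the atrium array of fish 4 at 20 °C at 73.4.

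Across the 3 compartments, hearts of warm-acclimated fish differed from those of cold-acclimated fish in 50.1% of the probes tested. The arrays of 14 and 25 °C fish shared no scan day, so temperature and scan day cannot be told apart in this contrast. Of the probes called, 65.7% were dim in a compared group, that is, well above background on fewer than 3 of its arrays. The share of dim probes among all probes tested is not given here. At 25 against 14 °C, 4968 probes were higher and 4857 lower, with a median change of 0.42 (log2 scale) among those past the threshold. With loess normalisation the larger changes were mostly falls: of the probes past the threshold, 1287 fell by more than 2-fold and 290 rose by more than 2-fold. Of the 7080 targets tested, 2343 rose and 1951 fell. Among the 5626 targets with at least 3 tested probes, all tested probes rose in 297 and all fell in 649. Probes of 1 target past the threshold in opposite directions occurred in 605 of the 2891 targets with several such probes.

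The 4 targets named by the rule for 25 against 14 °C moved the same way in all 3 compartments. TTC05580 fell by 2.88 on the log2 scale (SE 0.26, adjusted p = 3.7e-10), a 7.37-fold drop, and all 12 arrays at 25 °C lay below the 14 °C mean of their compartment. Its log2 ratio in the atrium went from 0.93 ± 1.1 (SD, n = 4) at 14 °C to -2.57 ± 0.26 at 25 °C, and in the spongy layer from 1.41 ± 0.86 to -1.44 ± 0.1. Arrays of day F raised both 14 °C means. In the atrium fish 1 lay at 2.60 and the other fish between 0.027 and 0.58. In the spongy layer fish 1 and 4 lay at 2.64 and 1.37, and fish 2 and 3 at 0.78 and 0.86. The probe that stands for it is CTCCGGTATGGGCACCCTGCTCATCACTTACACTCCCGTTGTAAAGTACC. TTC02637, measured by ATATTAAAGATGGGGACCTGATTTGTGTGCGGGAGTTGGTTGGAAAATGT, fell by 2.83 (SE 0.33, adjusted p = 3.1e-08, 12 of 12 arrays). Its log2 change was -4.01 in the atrium, -1.66 in the compact layer and -2.82 in the spongy layer. Arrays of day F raised its 14 °C means as well. In the atrium fish 1 lay at 2.171 and the other fish between -0.229 and 0.4075. In the compact layer fish 4 lay at 0.932 and the others between -0.0855 and 0.0316. In the spongy layer fish 1 and 4 lay at 2.132 and 1.345, and fish 2 and 3 at 0.3124 and 0.4191. TTC01112 rose by 1.40 (SE 0.098, adjusted p = 1.7e-12, 12 of 12 arrays), a 2.63-fold rise, by 1.63 in the atrium, 1.53 in the compact layer and 1.03 in the spongy layer. Its probe is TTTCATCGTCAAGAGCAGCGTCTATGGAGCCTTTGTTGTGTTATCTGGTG. TTC03742, measured by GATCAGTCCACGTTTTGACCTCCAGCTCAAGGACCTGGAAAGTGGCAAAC, rose by 1.29 (SE 0.12, adjusted p = 4.6e-10, 12 of 12 arrays), although its 3 probes ranged from 0.42 to 1.29. These 4 were the extremes of 62 eligible targets, 52 of which fell and 10 of which rose. The 12 arrays at 25 °C came from 4 fish. In a limma fit on the mean of each fish's tissues, the adjusted p values were larger. They were 3.8e-05 for TTC05580, 4.3e-05 for TTC02637, 6.5e-06 for TTC01112 and 2.4e-05 for TTC03742.

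**Figure D3:**
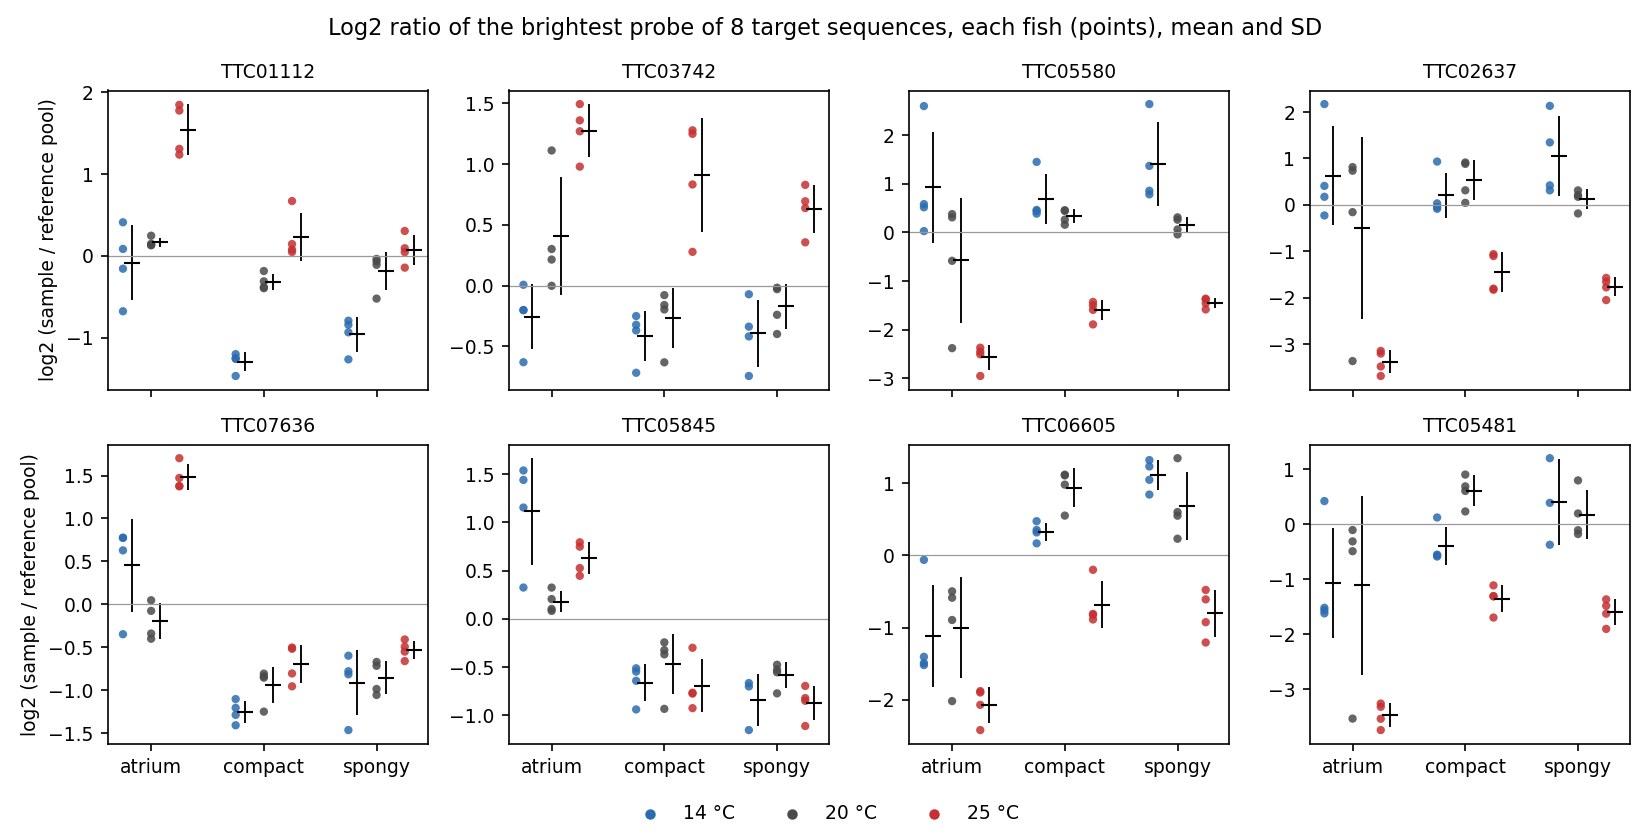
Log2 ratio of sample over reference pool (vertical axes, scaled separately) for the brightest probe of the 8 named targets in each compartment (horizontal axis); points are fish, coloured by temperature, and the bar beside each group is its mean and SD over 4 fish, or 3 where a spot was left out. TTC05580 in the atrium falls from a mean of 0.93 at 14 °C to -2.57 at 25 °C, and TTC07636 is 1.48 in the atrium at 25 °C against -0.69 in the compact layer.

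Within single compartments, the difference between 25 and 14 °C took in the most probes in the atrium with loess, but not with median centring. In the atrium 4800 probes rose and 5197 fell, 51% of those tested. In the compact layer 2119 rose and 1660 fell, and in the spongy layer 2028 rose and 2198 fell. In all 3 compartments 605 probes rose and 789 fell, and for 11 targets every probe rose in all 3 while for 38 every probe fell. With the scan day as a random block the counts were 6681 over the tissues, 8183 in the atrium, 1889 in the compact layer and 2231 in the spongy layer. Median centring in place of loess gave 6438 rises and 3911 falls over the tissues, 6686 calls in the atrium, 7114 in the compact layer and 1687 in the spongy layer. Removal of the GC trend gave 7618 rises and 4099 falls over the tissues and 7910 and 4406 in the atrium, while the filter for bright probes gave 719 and 1180 in the atrium. A fit of the compared groups alone gave 2020 rises and 2509 falls in the compact layer, and without the 4 arrays of day F 2199 were left in the spongy layer.

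**Figure D4:**
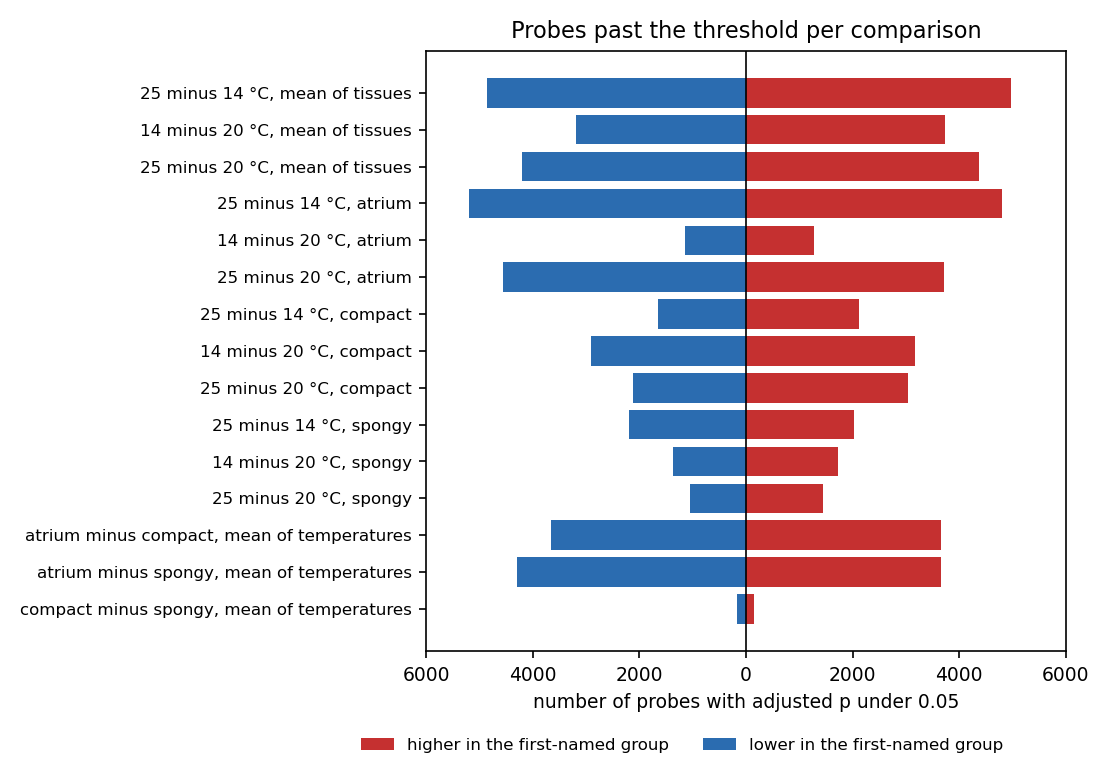
Number of probes past the threshold (horizontal axis) in each of 15 contrasts (vertical axis), higher in the first-named group to the right and lower to the left of 0. The contrast of 25 with 14 °C in the atrium has 4800 higher and 5197 lower probes, and that of the compact with the spongy layer 142 higher and 171 lower.

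Cold acclimation was compared with the intermediate temperature as 14 minus 20 °C. Over the compartments 3740 probes were higher at 14 °C and 3194 lower, 35.4% of those tested, with 384 of the higher and 68 of the lower by more than 2-fold. In the compact layer 3162 were higher and 2910 lower, in the spongy layer 1719 and 1363, and in the atrium 1273 and 1151. The compact layer had the highest count, except with array weights, which gave 8366 in the atrium and 8216 in the compact layer. TTC01112 was lower at 14 °C in the compact layer, -1.29 ± 0.12 (SD, n = 4) against -0.32 ± 0.096 at 20 °C. TTC05580 at 0.68 ± 0.51 in the compact layer at 14 °C and 0.33 ± 0.14 at 20 °C differed by less than the spread between fish. The changes of the compact and spongy layers correlated at r = 0.731 across probes, those of atrium and spongy layer at 0.383 and those of atrium and compact layer at 0.0261. Probes are not independent replicates. On scan day E the 20 °C arrays of compact and spongy layer shared a session and those of the atrium had another. An effect of the session could thus add to the higher correlation of the ventricular layers. At 20 °C both correlations with the atrium were between sessions. At 14 °C day F held 1 atrium, 1 compact and 2 spongy arrays in the same session. Whether this unequal share adds to the difference between the 2 correlations with the atrium was not tested. The scan day as a random block lowered the counts to 2385 over the tissues, 901 in the atrium, 4337 in the compact layer and 1134 in the spongy layer, and the direction turned to mostly lower under median centring, with 1463 higher and 3725 lower over the tissues. Other settings also changed the atrium counts. There 869 probes were higher and 1041 lower without the array of fish 4 at 20 °C, 179 and 1034 with the Agilent processed signals, and 358 and 395 in a fit of the compared groups alone. Median centring gave 3062 in the compact layer. In the spongy layer 1239 were called with the processed signals, 1982 without fish 4 at 14 °C and 1453 without fish 3 at 20 °C.

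Warm acclimation was compared as 25 minus 20 °C. Over the compartments 4371 probes rose and 4196 fell, 43.7% of those tested. In the atrium 3707 rose and 4570 fell, in the compact layer 3037 and 2113, and in the spongy layer 1438 and 1057. TTC05580 fell from 0.33 ± 0.14 (SD, n = 4) to -1.60 ± 0.2 in the compact layer and from 0.15 ± 0.17 to -1.44 ± 0.1 in the spongy layer. In the atrium its 20 °C mean was -0.57 ± 1.3, with fish 4 at -2.38 and the other fish between -0.58 and 0.38. TTC03742 stood at -0.27 ± 0.25 in the compact layer at 20 °C and at 0.91 ± 0.47 at 25 °C. The compact and spongy changes correlated at r = 0.798 across probes, and 1707 of the 1715 probes past the threshold in both had the same sign. Of these 1068 rose and 639 fell in both, where independent lists would share 223 and 114. All 20 °C arrays were scanned on day E, which held no other temperature, and compact and spongy arrays in 1 session of it, so an effect of that session would enter both changes and add to their correlation. With the scan day as a random block, 3388 probes were left over the tissues, 5627 in the atrium, 2587 in the compact layer and 568 in the spongy layer. Without the atrium array of fish 4 at 20 °C the atrium count was 9342, median centring there gave 1828 rises and 4634 falls, and removal of the GC trend 6503 rises and 4028 falls. The processed signals gave 1735 and 3470 in the atrium, a fit of the compared groups alone 2628 and 2191, and array weights 6707 and 6335. In the compact layer removal of the GC trend gave 2624 rises and 3113 falls, median centring 9771 calls and the processed signals 3278. In the spongy layer median centring gave 1072 and 1227, a fit of the compared groups alone 2328 and 2642, and array weights 5916 calls. In that layer 1411 probes were called without fish 3 at 20 °C, 1635 without fish 1 at 25 °C and 1644 without fish 3 at 25 °C.

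The measured change with temperature differed between the compartments for 8500 probes, 43.4% of those tested, by the F test of the tissue by temperature terms. Scan days and sessions were not balanced over compartment and temperature, so their effects can enter this count. The change from 14 to 25 °C differed between atrium and compact layer for 6303 probes, between atrium and spongy layer for 4817, and between compact and spongy layer for 116. Among the 8500, the atrium had the largest of the 3 changes in 67.3%. TTC01112 was among them (adjusted p = 0.0032), as were TTC07636 (adjusted p = 0.00043) and TTC05845 (adjusted p = 0.0046), while TTC05580 was not (adjusted p = 0.41). The 25 minus 14 °C changes still shared their direction: those of atrium and spongy layer correlated at r = 0.702 across probes, those of atrium and compact layer at 0.53, and those of compact and spongy layer at 0.769. Of the 2480 probes past the threshold in both atrium and compact layer, 84.1% had the same sign, and 1048 rose in both where independent lists would share 519. These correlations use different arrays of the same fish, and the compartments shared scan days: day D held all atrium and compact arrays of 25 °C fish, day F arrays of all 3 compartments at 14 °C, and day B compact and spongy arrays at 14 °C. A day effect common to the arrays of a day would add to these correlations. With the scan day as a random block 7675 probes passed the F test, with the scan session 6261, with median centring 4264, and with array weights 13868.

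The arrays of atrium and ventricular layers differed at each of the 3 temperatures. Only atrium and compact layer at 25 °C were compared within 1 scan session. At 14 °C 3 of the 4 atrium arrays were scanned on day A, which held no ventricular array. At 25 °C the atrium arrays were scanned on day D and the spongy arrays on day C. At 20 °C the atrium arrays had a session of their own. In those comparisons tissue is mixed with scan day or session. As a mean over temperatures, 3663 probes were higher in the atrium than in the compact layer and 3667 lower, and 3657 were higher and 4304 lower than in the spongy layer. Against the spongy layer, removal of the GC trend turned this to 5514 higher and 3339 lower, and the filter for bright probes gave 499 and 1130. Against the compact layer that filter gave 513 and 1006. TTC07636 was higher in the atrium than in the compact layer by 1.54 (log2 scale, SE 0.11, adjusted p = 4.4e-12, 12 of 12 arrays). It stood at 1.48 ± 0.15 (SD, n = 4) in the atrium at 25 °C against -0.69 ± 0.22 in the compact and -0.53 ± 0.11 in the spongy layer, and its probe is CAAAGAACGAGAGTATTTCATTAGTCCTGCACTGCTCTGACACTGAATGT. TTC05845 was higher by 1.25 (SE 0.11, adjusted p = 4.9e-10, 12 of 12 arrays), most of all at 14 °C, where the atrium was at 1.11 ± 0.55 and the compact layer at -0.66 ± 0.19. TTC06605 was lower in the atrium, with a log2 change of -1.59 (SE 0.17, adjusted p = 1.3e-08, 12 of 12 arrays), and its probe is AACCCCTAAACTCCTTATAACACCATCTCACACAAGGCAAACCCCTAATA. TTC05481 changed by -1.50 (SE 0.29, adjusted p = 0.00014, 11 of 12 arrays) and in the atrium at 25 °C reached -3.47 ± 0.22.

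The gap between atrium and compact layer was widest at 25 °C. It took in 3760 probes at 14 °C, 4733 at 20 °C and 8801 at 25 °C, and the SD of the difference over all probes was 0.5, 0.437 and 0.708 on the log2 scale. Over the 2554 probes well above background in both channels on all arrays that SD was 0.884, 0.684 and 1.18, with 977, 723 and 1675 calls, so by SD and by bright probes the gap was narrower at 20 than at 14 °C. Within the scan day that held both tissues of the 25 °C fish, 7600 probes differed between atrium and compact layer, all in 1 scan session. Within the day of the 20 °C fish 2517 differed, and 1445 between atrium and spongy layer, but there all atrium arrays were in 1 session and all compact and spongy arrays in another, so tissue and session cannot be told apart at 20 °C. A fit of tissue with the scan day as a fixed block gave 6408 probes for atrium minus compact layer and 3233 for atrium minus spongy layer. With the scan session as the fixed block it gave 6758 and 4428. These fits held no temperature terms, so they rest on arrays that shared a day or session and are not means over temperatures. Atrium and compact arrays shared a session only at 25 °C and, with 1 array of each, at 14 °C. In fits of the compared tissues alone with each fish as a fixed block the mean contrasts gave 2578 and 4966.

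Compact and spongy layers were close to each other. As a mean over temperatures, 142 probes were higher in the compact layer and 171 lower, 1.6% of those tested, and for 13 targets all probes were higher and for 4 all were lower. None of the 8 named targets passed the threshold between them, the lowest of their adjusted p values in limma being 0.41, for TTC07636, with a change of -0.19. At single temperatures 559 probes differed at 14 °C, 52 at 20 °C and 333 at 25 °C, where the layers were scanned on different days. Within the scan session of both layers of the 20 °C fish, limma called 0 probes, with 2163 under an unadjusted p of 0.05, and within the 1 day with several arrays of both layers from 14 °C fish it called 2678, from 3 against 2 arrays. The fit of tissue with the scan day as a fixed block, which is not a mean over temperatures, gave 121 probes. The Agilent processed signals gave 5843, the values of the series table gave 5541, median centring in place of loess 3001 and array weights 1092, so the count for this pair depended on the setting. Leaving out 1 fish moved it by over 1.5 times for fish 2 at 14 °C (201 probes), fish 1 at 20 °C (181) and fish 1, 2 and 3 at 25 °C (205, 177 and 171).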

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

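The tests of the atrium array of fish 4 at 20 °C, the tests and the grouping of the arrays scanned on day F other than that of compressed ratios, and the tests of the larger change in the atrium were chosen after the result they bear on, or values close to it, had been seen. The test of compressed ratios, except for its form with no array on both sides, and the counts over other groupings of the arrays were set before their results were seen.

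A sample far from the other 3 of its group was found in 20 of 106 groups of values tested, where chance gives about 5.3, so single cases carry little weight. Many fall on a few arrays. The compact array of fish 4 at 14 °C had a median reference signal of 127.4 scanner units against 71.22 to 79.65 in the others, a mean correlation with its group of 0.602 against 0.782 to 0.809, and log2 ratios of 1.45 for TTC05580, 0.93 for TTC02637 and 0.125 for TTC05481, each above the other fish. The atrium array of fish 1 at 14 °C had a mean correlation with its group of 0.487 against 0.763 to 0.774, a first principal component of -61.5 against -11.1 to -10.4, and log2 ratios of -0.35 for TTC07636, -0.0632 for TTC06605 and 0.42 for TTC05481. The atrium array of fish 4 at 20 °C had a mean correlation of -0.0372 with its group against 0.379 to 0.402, and log2 ratios of -3.54 for TTC05481 and 0.25 for TTC01112.

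The remaining cases are spread over other arrays. Mean correlations with the group were 0.559 for the spongy array of fish 2 at 14 °C, 0.698 for the compact array of fish 1 at 20 °C and 0.516 for the compact array of fish 4 at 25 °C. Log2 ratios far from the other 3 fish were -0.52 for TTC01112 in the spongy layer of fish 3 at 20 °C, 0.67 for TTC01112 in the compact layer of fish 4 at 25 °C, -1.25 for TTC07636 in the compact layer of fish 4 at 20 °C and -0.20 for TTC06605 in the compact layer of fish 3 at 25 °C.

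The atrium array of fish 4 at 20 °C correlated at 0.874 on average with the atria at 25 °C. A swap with a 25 °C atrium is argued against, since 0 of the 4 atria at 25 °C lay closer to the 20 °C atria of fish 1 to 3 than to each other. A heart that was warm-like as a whole is argued against as well: the compact and spongy arrays of the same fish lay at -0.118 and 0.122 of the way from the other fish at 20 °C to the 25 °C mean of their layer. A single wrong label may be the source, since the array lay at 0.872 of the way and the atria at 25 °C between 0.833 and 1.10. A state of that atrium alone stays open as well and was not tested.

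The 4 arrays of 14 °C fish scanned on day F differed from the other 14 °C arrays in 2629 of 17998 probes, and 1 of 96 choices of arrays, the real one, gave as many, the highest other giving 0. A difference between the fish is argued against, since the arrays of the same fish scanned on other days lay at 0.00809 and 0.054 of the spongy layer's day F difference. Compressed ratios on dimmer arrays as the whole cause are argued against, since the difference correlated with the mean log ratio of the other arrays at -0.148 in the atrium, -0.135 in the compact and 0.178 in the spongy layer, and at -0.12, -0.0942 and 0.277 with no array on both sides of the correlation. Compression in part stays open: an offset of 0 lowered the count to 1696, and the SD of the log ratios was larger on day F arrays, 0.582 against 0.379, 0.406 against 0.308 and 0.488 against 0.261. The scan day, with whatever handling went with it, may be the source: the day F arrays lay at 1.07 in the atrium and 0.356 in the compact layer, and with 1 array of each tissue that value between the bounds set keeps it open. The day F difference correlated at -0.574 across probes with the change from 20 to 25 °C, so it lies along an axis that temperature also uses.

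The measured changes with temperature differed between tissues, although scan days and sessions were not balanced over tissue and temperature. By the F test of the tissue by temperature terms 8500 probes differed, and the 25 minus 14 °C change differed in 6303 probes between atrium and compact layer, in 4817 between atrium and spongy layer and in 116 between the ventricular layers. Among the named targets the adjusted p from limma was 0.0032 for TTC01112, 0.00043 for TTC07636 and 0.0046 for TTC05845, with the 25 minus 14 °C changes of TTC01112 at 1.63 in the atrium, 1.53 in the compact and 1.03 in the spongy layer. Those of TTC07636 were 1.02, 0.56 and 0.39, and those of TTC05845 -0.49, -0.03 and -0.03. The F test also takes in the 20 °C arrays. In the same order of tissues, the 25 minus 20 °C changes were 1.38, 0.553 and 0.259 for TTC01112. They were 1.67, 0.242 and 0.328 for TTC07636, and 0.45, -0.224 and -0.287 for TTC05845.

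The larger change of the atrium at 25 °C was weighed as the pattern behind these counts. An effect of the scan day added to all its arrays is argued against only for 20 against 25 °C in atrium and compact layer. There the atrium minus compact difference, taken within 1 day at each temperature, changed in 5317 probes. Without the atrium array of fish 4 at 20 °C it changed in 7009. This holds as far as a day acts as 1 unit. For the 25 minus 14 °C counts such an effect stays open. At 14 °C 3 of the 4 atrium arrays were scanned on day A, which held no ventricular array. At 25 °C the atrium was scanned on day D and the spongy layer on day C, so the test does not reach that pair. An effect of the scan session stays open, since at 20 °C the atrium and the compact layer were in different sessions. With the session as a fixed block the 25 minus 14 °C change differed between atrium and compact layer in 4393 probes, but that rests on 1 array of each tissue at 14 °C, from different fish, assumed to vary like the others. Brighter atrium arrays with compressed ratios in the layers are argued against, since over bright probes with an offset of 0 the SD of the 25 minus 14 °C change, corrected for error, was 1.89 times that of the layer with the larger SD. Probe GC content is argued against as the whole cause, since that ratio was 1.80 with the GC trend of each array removed. The normalisation stays open, since median centring in place of loess gave 6686 probes for 25 minus 14 °C in the atrium and 7114 in the compact layer. A larger response of the atrium to warmth, a scan day effect specific to a tissue and a difference in the cell types sampled stay open too and were not tested.

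Chance in the grouping of the samples was tested over the 17998 probes complete on all arrays, by exchanging fish between the temperatures compared. For each of the 12 temperature contrasts 1 of the 35 splits of 8 fish, the real one, gave as many probes. That is the smallest share that 35 splits can give, so chance is argued against but not excluded. The real split also separates the scan days, so its rank cannot tell temperature from scan day. Over the tissues the real splits gave 8670 probes for 25 minus 14 °C, 6222 for 14 minus 20 °C and 7471 for 25 minus 20 °C, and the highest others 48, 886 and 3464. In the atrium they gave 8831, 2130 and 7235, with 2795, 2013 and 6510 as the highest others. In the compact layer they gave 3149, 5432 and 4424 (165, 922 and 1980), and in the spongy layer 3603, 2876 and 2070 (3, 22 and 22). The split with 6510 probes exchanged fish 4 at 20 °C, the array that lies with the 25 °C atria. The split with 2013 probes set the 3 atria of day A and fish 4 at 20 °C against the rest, so it nearly follows a scan day, and with the scan day as a random block 901 probes were called.

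For the tissue contrasts, labels were exchanged within fish in 100 groupings, the real one included. The real grouping gave 6425 probes for atrium minus compact layer and 7013 for atrium minus spongy layer, each the only 1 of 100 with as many, against 4591 and 5501 in the highest others. For compact minus spongy layer it gave 247, and 2 of 100 gave as many, the other with 292 probes by exchanging fish 4 at 20 and at 25 °C. For the tissue by temperature terms it gave 7582, as 1 of 100, against 5627. By this measure chance is argued against for atrium minus compact and atrium minus spongy layer. For compact minus spongy layer another grouping gave more probes than the real one, so chance is not excluded. For the tissue by temperature terms, permuted tissue labels also break up the mean difference between tissues. That test therefore cannot decide whether these terms arose by chance. Why the grouping with 292 probes exceeded the real one was not tested.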

How the results depend on the processing

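The offset of 0, the removal of the GC trend, the fits without the atrium array of fish 4 at 20 °C or the arrays of day F, the scan session as a block, the scan day as a fixed block and the mean of a target's probes were tests chosen after the results were seen. A count is said to move where it changed by over 1.5 times.

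No count moved without background subtraction, without the filter, without the fish, with an offset of 0, with the GC trend removed or without the atrium array of fish 4 at 20 °C. Aquantile leaves the log ratios unchanged and tests nothing here. With the replicate number as a fixed block, 25 minus 14 °C over the tissues gave 9895 probes against 9825, and no other count moved. All 8 named targets kept their direction and their side of the threshold under every alternative run. TTC05481 lay between -1.69 and -0.83 with a highest adjusted p of 0.026. Sizes moved: TTC07636 lay between 1.05 and 2.36 and TTC05845 between 0.77 and 2.08, the upper ends under median centring, and TTC06605 between -1.72 and -0.99.

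The scan day as a random block moved 14 minus 20 °C to 2385 over the tissues, 901 in the atrium and 1134 in the spongy layer. It moved 25 minus 20 °C to 3388 over the tissues, 2587 in the compact and 568 in the spongy layer, 25 minus 14 °C to 1889 in the compact and 2231 in the spongy layer, and compact minus spongy layer to 146. As a fixed block, in a fit without temperature terms, it gave 3233 for atrium minus spongy and 121 for compact minus spongy layer. The scan session as a random block gave 3640, 977 and 1236 for 14 minus 20 °C over the tissues, in the atrium and in the spongy layer, 4740, 2766 and 649 for 25 minus 20 °C over the tissues, in the compact and in the spongy layer, 2029 and 2371 for 25 minus 14 °C in compact and spongy layer, and 151 for compact minus spongy layer. As a fixed block, in a fit without temperature terms, it gave 4428 for atrium minus spongy and 151 for compact minus spongy layer. The cause was not tested. Without the 4 arrays of day F, the spongy layer gave 2199 for 25 minus 14 °C and 1574 for 14 minus 20 °C, from fewer samples.

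The Agilent processed signals gave 1213 for 14 minus 20 °C and 5205 for 25 minus 20 °C in the atrium, 3278 for 25 minus 20 °C in the compact layer, 1239 for 14 minus 20 °C in the spongy layer and 5843 for compact minus spongy layer. The series table gave 975 and 1048 for 14 minus 20 °C in atrium and spongy layer and 5541 for compact minus spongy layer. Median centring in place of loess gave 7114, 3062 and 9771 for 25 minus 14, 14 minus 20 and 25 minus 20 °C in the compact layer, 1687 for 25 minus 14 °C in the spongy layer, 4264 for the tissue by temperature terms, 11123 for atrium minus compact and 3001 for compact minus spongy layer. The cause was not tested.

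Array weights gave 8366 for 14 minus 20 °C and 13042 for 25 minus 20 °C in the atrium, 5916 for 25 minus 20 °C in the spongy layer, 13868 for the tissue by temperature terms and 1092 for compact minus spongy layer. Fits of the compared groups alone gave 753 for 14 minus 20 °C and 4819 for 25 minus 20 °C in the atrium, 4970 for 25 minus 20 °C in the spongy layer, and 2578, 4966 and 152 for atrium minus compact, atrium minus spongy and compact minus spongy layer. For both the cause was not tested.

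Only 2554 probes were well above background in both channels on all 36 arrays, and this filter lowered all 16 counts, since fewer probes were tested. For 25 minus 14, 14 minus 20 and 25 minus 20 °C it gave 1885, 1118 and 1757 over the tissues, 1899, 622 and 1708 in the atrium, 990, 1025 and 1200 in the compact layer and 1102, 352 and 736 in the spongy layer. It gave 1677 for the tissue by temperature terms and 1519, 1629 and 85 for the tissue contrasts in the same order. Signal over background limits the rest: 65.7% of the probes called for 25 minus 14 °C over the tissues were dim in a compared group.

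Directions moved too. For 14 minus 20 °C over the tissues, 3740 up and 3194 down became 3036 and 4831 with the GC trend removed. In the atrium 1273 and 1151 became 179 and 1034 with the processed signals and 268 and 1561 with median centring, and in the spongy layer 1719 and 1363 became 766 and 1834 with median centring. The median of all probes shifted by over 0.1 (log2) in some, by -0.16 for 14 minus 20 °C in the atrium with the processed signals. The direction with more probes turned under at least 1 alternative in each of the 15 contrasts, so it is not settled.

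Leaving out each fish in turn gave, for 25 minus 14, 14 minus 20 and 25 minus 20 °C, 9029 to 9859, 5714 to 7033 and 7289 to 8861 over the tissues. In the atrium it gave 8933 to 10151, 1755 to 2621 and 6519 to 9262, in the compact layer 2970 to 4452, 5089 to 6261 and 4125 to 5360, and in the spongy layer 3085 to 4992, 1453 to 3233 and 1411 to 2851. It gave 6945 to 9258 for the tissue by temperature terms, and 6400 to 7507, 7019 to 8151 and 171 to 439 for atrium minus compact, atrium minus spongy and compact minus spongy layer. Counts moved for 14 minus 20 °C in the spongy layer without fish 4 at 14 °C (1982) or fish 3 at 20 °C (1453), for 25 minus 20 °C there without fish 3 at 20 °C (1411), fish 1 at 25 °C (1635) or fish 3 at 25 °C (1644), and for compact minus spongy layer without fish 2 at 14 °C (201), fish 1 at 20 °C (181) or fish 1, 2 or 3 at 25 °C (205, 177, 171).

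Not run were the gene and marker lists with their set tests and the genes named by symbol, since the files used here pair no probe with a gene, the slide as a block, and a fit of the compared groups alone for the tissue by temperature terms.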

Other observations

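The tests of the order of temperatures were chosen after the data were seen. Among the probes past the F test over temperatures within a tissue, the 20 °C mean lay between the other means in 68.6% of 10533 probes in the atrium, 21.9% of 7922 in the compact layer and 48.2% of 5769 in the spongy layer. Without the array of fish 4 at 20 °C, which lies with the 25 °C atria, the atrium's share was 52.1% of 11005. In the compact layer the 25 °C mean lay in the middle in 49.4%. Over bright probes past the test, the shares with 14, 20 and 25 °C in the middle were 35.9%, 29.1% and 35% there. All 20 °C arrays share 1 scan day, so a day effect and an effect of 20 °C on this order cannot be told apart.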
